A study of Arabidopsis thaliana with 3 samples.

How the data were processed

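Chromatin immunoprecipitation followed by sequencing was carried out on 14-day-old seedlings. Per the labels' protocols, tissue was crosslinked with formaldehyde, chromatin was sonicated, and DNA was recovered with an antibody against GFP from 2 immunoprecipitates of dek2-1 plants with a DEK2-YFP transgene; 1 input sample of the same plants was made without antibody. The design text of the series also speaks of wild-type and dek2-1 plants under mock and bacterial treatment, but the labels of these 3 samples name no such group, and those groups were not analysed here.

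The submitters' processing notes list Trimmomatic 0.38, Bowtie2 2.3.5, SAMtools 1.9 and MACS2 2.2.7.1 and the TAIR10 build, without giving their roles or settings. The deposited files are 1 peak list for each immunoprecipitate, so peaks were called by the authors per sample and not on pooled samples. Columns were read by their place in the narrowPeak format, since the files carry no header. The score of each deposited peak is a whole number made from its q value. The fold enrichment deposited for each peak is a ratio of the pileup at the summit to the modelled background. The p-value and q-value columns hold deposited −log10 values, and no deposited peak had a −log10 q under 1.30. Whether the input served as the control for peak calling, how reads with several matches were treated and whether duplicates were removed is not given in the sources used here.

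Depth was worked out from the peak values, since no read counts were used here. The fold enrichment and p-value of each peak were solved for pileup and background under MACS2's own formulas, a ratio with 1 added to both and a Poisson tail. All peaks of both lists gave a solution. Pileups came out whole, within 0.02, in 100% of the replicate 2 peaks and 8.08% of the replicate 1 peaks, whose steps fit a scaling of 0.894. The commonest background was 54.1 in replicate 1 (60.5 unscaled) and 22.1 in replicate 2. Smallest peak widths of 210 and 150 bp, taken as fragment lengths, put the ratio of reads at 1.95. Greater depth lets weaker enrichment pass the threshold, so numbers and widths of peaks are not comparable between the replicates.

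Gene names, spans and classes came from a RefSeq gene table of the assembly TAIR10.1, which holds 37887 nuclear genes. It gives neither strand nor exons nor sequence, and no genome sequence was used. Because the labels name TAIR10, none of its coordinates is printed, and the placing of peaks in genes rests on a check. When the shared summits were moved in steps of 50 bp, the share inside gene spans had its minimum at 0 over all chromosomes, and in 25 of 25 blocks of 5 Mb the minimum lay within 150 bp of 0. Peaks and gene spans are thus in register at that scale, and distances of a few base pairs rest on the table.

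A replicate 1 peak counted as shared when it overlapped a replicate 2 peak by at least 50% of the shorter. Chance was estimated from 1000 circular shifts along each chromosome. The planned classes by transcription start, untranslated region, exon and intron were replaced by classes of distance to gene ends. The planned rule for a bound gene, from 500 bp upstream to the gene end, was replaced by a summit inside or within 500 bp of either end; this was settled after the table had been seen to lack strand and after summit positions had been looked at, before any list was tested. The fold given for replicate 2 is that of the matching peak, wherever its own summit lies. Lists of genes were tested with an exact test that draws members within 20 bins of gene length (sums of hypergeometric counts, two-sided by doubling the smaller tail), with Benjamini-Hochberg adjustment over 18 lists and 9 families. Of the list members 372 matched the table by name and locus and 36 by locus alone; 1 locus was not analysed here. Shares have 95% Wilson intervals unless stated, which cover counting error only. The gene lists, the list test and the first set of alternatives were fixed before the data were examined; the rule for a bound gene and the location classes, as used, were not.

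Genes are named by a rule fixed in advance: DEK2 and its 3 relatives; the 10 genes with the best shared peaks, ranked by the worse of the peak's ranks of fold enrichment within the replicates; the best 3 bound members of each immunity list (2 are given for NLR receptors) and the best 2 of each other list; FLS2, BAK1, FRK1, WRKY33, ICS1, PR1, NPR1, EDS1, FLC and ACT2 in any case; and the 2 longest unbound members of a list bound less often. Other genes were chosen after their values were seen.

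The code was tested on simulated data. All of 1200 simulated shared peaks among 3000 were recovered. For the gene list test, 500 simulated lists of 25 genes without effect gave a p under 0.05 in 3.4% of lists, and in 3.8% when long genes were drawn, where Fisher's exact test without length bins gave 12%. The same test found 87.2% of 500 lists with 4-fold odds of being bound and 66.2% of 500 lists with odds reduced to 1/4. In these simulations each gene was bound independently of its neighbours, while 24.1% of the real shared peaks lay near more than 1 gene. The simulated rates therefore do not cover lists or families whose members lie side by side. For the location of peaks, 100 simulated sets of 2000 summits gave a p under 0.05 in 5% of sets without preference and in 100% when 30% of summits had been moved into genes. Background was recovered within 1% for 100% of 500 simulated peaks.

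Alternatives covered stricter q values, other overlap rules, equal numbers of peaks, each replicate alone, peak midpoints, other windows, other rules for a bound gene, no length correction and random placement. Summits inside the gene, the nearest gene, peaks near 1 gene only and, for the gene classes, Fisher's exact test without length bins were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.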

Results

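AtDEK2 (AT5G63550) is 1 of 4 DEK-type chromatin proteins of Arabidopsis thaliana, and the title of the series ties it to the reading of histone marks and to immunity. Chromatin of 14-day-old seedlings was immunoprecipitated with an antibody against GFP, which also recognises YFP, from dek2-1 mutants that carried a DEK2-YFP fusion under the DEK2 promoter. The group holds 2 replicates, each with its own peak list, and 1 input sample of the same plants has no values used here. Immunoprecipitates from plants without the tagged protein were not analysed here, so every peak below is a place enriched over the background that the peak caller modelled, not over a mock immunoprecipitation. The labels number the replicates without saying whether their plants were grown apart, so the spread between them may be technical. All coordinates are TAIR10, counted from 1.

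Replicate 1 held 25742 peaks on the 5 nuclear chromosomes and replicate 2 held 13307. The peaks of replicate 1 covered 14217424 bp (11.9% of the chromosome length) with a median width of 465 bp, and those of replicate 2 covered 4063114 bp (3.41%) with a median width of 259 bp. Fold enrichments, which are the authors' own value for each peak, were low in both lists. Their median was 1.82 and their maximum 4.17 in replicate 1, against 2.02 and 4.98 in replicate 2. The read depth is not given, but the commonest background that the peak values imply was 60.5 fragments in replicate 1 before scaling (7.90% of its peaks) and 22.1 in replicate 2 (25.3%), a ratio of 2.73.

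The first question was which places of the genome were marked in both immunoprecipitates. Shared peaks numbered 10812, which is 42.0% of the replicate 1 peaks (95% Wilson interval 41.4 to 42.6), and 11834 replicate 2 peaks (88.9%, 88.4 to 89.5) were found again in replicate 1. Their summits lay a median of 69 bp apart. Protein-coding genes were ranked by their best shared peak, taking the worse of its ranks, which leaves out the 2424 shared peaks near no such gene. The first peak lay on chromosome 1 from 23473441 to 23474335, beside the neighbouring genes AT1G63290 and AT1G63295. It had a fold enrichment of 3.81 in replicate 1 and 3.79 in replicate 2. The next genes were AT1G76170 and ERD14 (AT1G76180), a dehydrin gene, beside a peak on chromosome 1 from 28586143 to 28588031 with 3.52 and 3.34. A peak on chromosome 4 from 16354217 to 16358039 had its summit 44 bp inside CYCD3;1 (AT4G34160), a D-type cyclin gene, and 5 bp outside AT4G34150, with 3.32 and 3.39. The remaining genes among the best 10 were HMA3 (AT4G30120) and AT4G30130, which share a peak of 3.302 in replicate 1 (the matching replicate 2 peak of 3.47 has its summit near AT4G30130 and over 500 bp from HMA3), AT1G69980 with 4.16 and 3.24, and AT5G11220 with 3.29 and 3.43.

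Circular shifts of the replicate 2 peaks along each chromosome gave 1628 ± 122 shared peaks (SD, 1000 shifts), so the observed number was 6.64 times chance (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Stronger replicate 1 peaks were found again more often. The share went from 14.2% (12.9 to 15.6) in the weakest of 10 equal groups by fold enrichment to 89.7% (88.5 to 90.8) in the strongest, while in replicate 2 it lay between 82.6% and 98.3% in each of its 10 groups. Across the shared peaks, which are not independent of each other, the fold enrichments of the replicates correlated weakly (Spearman 0.323, Pearson 0.330 on the log2 scale). At a −log10 q of at least 5 in both lists 3502 peaks were shared, and 4917 were shared with an overlap of at least 50% of both peaks.

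**Figure D1:**
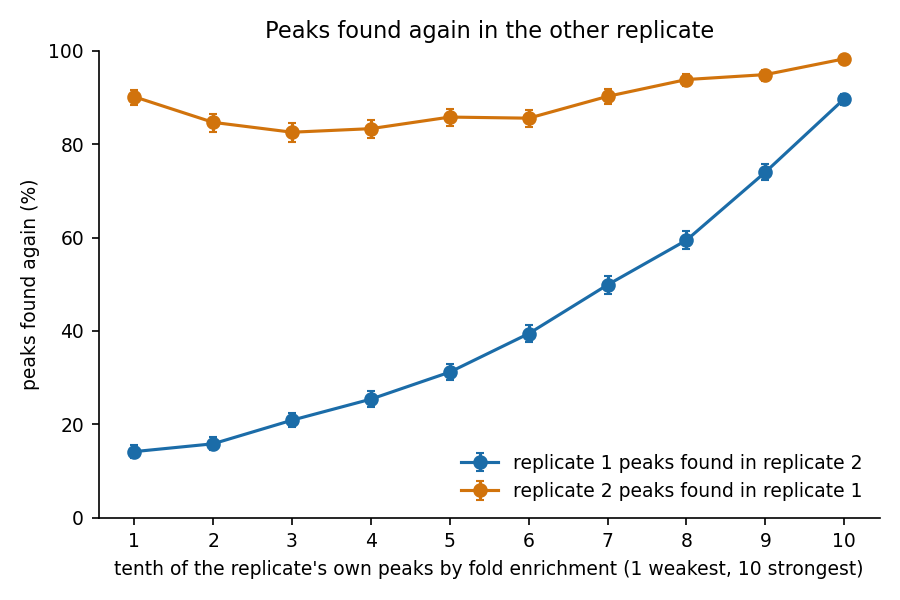
Share of peaks found again in the other replicate (y axis, %, with 95% Wilson intervals) for 10 equal groups of the replicate's own peaks ordered by fold enrichment (x axis). Replicate 1 peaks go from 14.2% in the weakest group to 89.7% in the strongest, and replicate 2 peaks lie between 82.6% and 98.3%.

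Shared peaks sat at the ends of protein-coding genes and avoided gene interiors. Summits inside a gene and within 500 bp of its end made up 35.8% of the 10812 shared peaks (34.9 to 36.7), against 21.3% ± 1.00 (SD) in 1000 sets of shifted summits, and summits outside genes but within 500 bp of one made up 36.3% (35.4 to 37.3) against 13.3% ± 0.480. Only 5.46% (5.04 to 5.90) lay inside a gene more than 500 bp from both ends, where shifted summits fell in 33.0% ± 1.66 of cases. Other annotated genes, counted only where they lie over 500 bp from any protein-coding gene, held 1.89% (1.65 to 2.16) against 9.22% ± 1.46. Summits in other genes closer to a protein-coding gene fell in the classes above, so this share does not describe other genes as a whole. Each of these 4 classes differed from chance (two-sided permutation test, adjusted p = 0.0025 over 5 classes), and the intergenic share of 20.5% against 23.2% ± 1.496 did not (adjusted permutation p = 0.102).

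The median distance of a summit to the nearest gene end was 172 bp, and 72.6% of summits lay within 500 bp of one. Among the 4369 summits inside genes of at least 1 kb, the 10% of gene length at each end together held 70.9% (69.5 to 72.2, exact binomial interval), where equal shares would give 20%, and parts 4 to 7 of 10 equal parts held 8.61% (7.79 to 9.48). The end at the lower coordinate held 34.7% and the end at the higher coordinate 36.1%. The reference table used for gene spans gives no strand, so transcription start and end sites could not be told apart, nor exons, introns and untranslated regions. With windows of 1000 bp, the class inside genes and near an end no longer differed from chance (38.8%, adjusted permutation p = 0.358), and the intergenic share was then lower than chance (12.1%, adjusted permutation p = 0.005). Over 8 alternatives the adjusted permutation p of these classes ran from 0.002 to 0.358 and from 0.002 to 0.823.

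**Figure D2:**
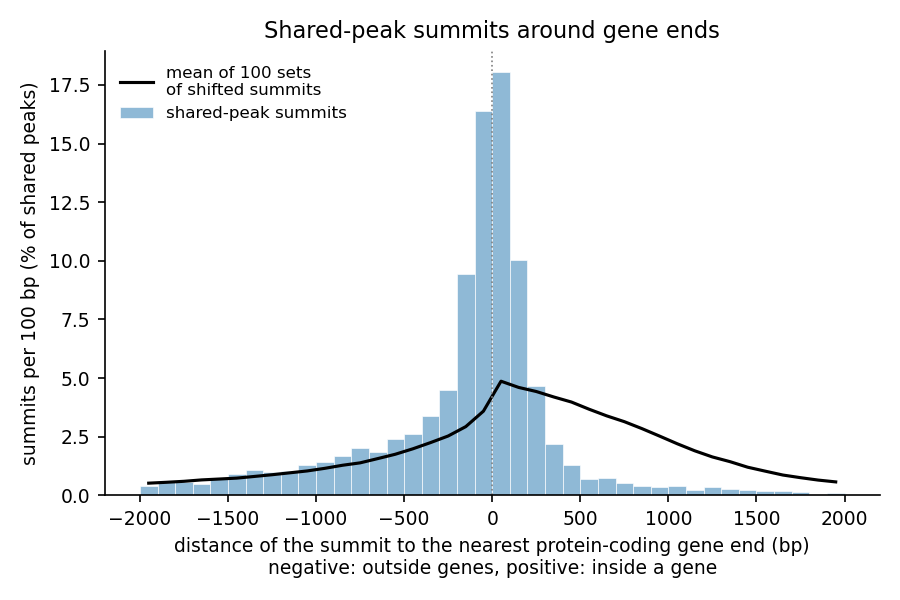
Shared-peak summits per 100 bp (bars, % of 10812 shared peaks) by distance to the nearest end of a protein-coding gene (x axis, bp, negative outside genes and positive inside), with the mean of 100 sets of shifted summits as a line. The bins on both sides of the gene end hold 16.4% and 18.1% of the summits against 3.59% and 4.87% of the shifted ones.

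Along the chromosomes, shared peaks were dense where protein-coding genes are dense. The 162 windows of 100 kb richest in genes held a mean of 11.9 shared peaks for 33.7 genes, and the 121 poorest held 0.116 for 2.76 genes. Over all 1188 windows the number of peaks and the number of genes correlated (Spearman 0.558, Pearson 0.657, two-sided permutation p = 0.000999 for the former from 1000 circular shifts, the smallest they can give; windows are not independent replicates).

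The next question was which genes carried a shared peak. A shared-peak summit lay inside or within 500 bp of 9374 of the 27432 nuclear protein-coding genes (34.2%, 33.6 to 34.7), termed bound genes here as a name for that position only. Replicate 1 alone gave 18291 such genes and replicate 2 alone 10160. Summits inside the gene were found in 4193 (15.3%), and 24.1% of shared peaks lay near more than 1 gene, which leaves open the gene they belong to. Among the genes named below this holds for the peaks of ACT2, EF1A1, HTR3 (3 other genes), RPL5B, RPL10A, REF6, MET1, PIF5 and EXPA7, and for others where stated. Bound genes had a median length of 2391 bp and the others 1900 bp, so gene lists were compared with genes of their own length. Place along the chromosomes was not matched.

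DEK2 itself had no shared peak and 1 peak of replicate 2 with a fold enrichment of 1.41. Of the related genes, DEK3 (AT4G26630) had a shared peak on chromosome 4 from 13429892 to 13430437, whose summit lay 189 bp outside the gene and also near AT4G26620, with 2.06 in replicate 1 and 1.75 in replicate 2. DEK1 (AT3G48710) had 1 peak and DEK4 (AT5G55660) had 2 peaks in replicate 1 and none in replicate 2.

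Among the 6 immunity lists fixed before the data were examined, the jasmonate and ethylene pathways carried more bound genes than genes of their length. In this list 20 of 28 genes were bound against 10.7 expected (exact length-stratified test, Benjamini-Hochberg adjusted p = 0.00362 over 18 lists and 9 families). The bound members included MYC2 (AT1G32640), the central transcription factor of jasmonate signalling, with a summit 538 bp inside the gene and also near AT1G32630, on chromosome 1 from 11798284 to 11799413 and folds of 2.99 and 2.66. JAZ6, a jasmonate repressor gene, had 2.56 and 3.25, and the ethylene transcription factor gene EIN3 had 2.39 and 2.43. In all, 8 JAZ genes of the list were bound, while EIN2, ETR1, MYC4, LOX2, OPR3 and the response genes VSP1, VSP2 and PDF1.2 were not. The call ended in 3 of 12 alternatives, among them a −log10 q of at least 5 in both replicates and reciprocal overlap. The former left 10 bound (2.53 times expected against 1.86 in the main test, adjusted exact p = 0.0626). The latter also left 10 bound (1.899 times expected, adjusted exact p = 0.199). The adjusted exact p ran from 0.0005 to 1.

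The other 5 immunity lists did not pass this test, although pattern-recognition receptors passed in 7 of 12 alternatives, early elicitor-responsive genes in 4 and salicylic acid in 1. Pattern-recognition receptors and early signalling had 16 of 25 genes bound against 10.3 expected (adjusted exact p = 0.0832), with RIN4, a target of bacterial effectors, at 2.89 and 3.04, CPK28 at 2.59 and 2.40, and CPK5 at 2.54 and 2.52. Early flagellin- and elicitor-responsive genes had 12 of 21 bound against 6.68 (adjusted exact p = 0.0720), with WRKY18 at 2.36 and 2.46, ERF104 at 2.50 and 2.19, and CYP81F2, whose peak also lies near AT5G57230, at 2.19 and 4.50. Salicylic acid synthesis and response had 15 of 26 bound against 10.1 (adjusted exact p = 0.150), with the receptor gene NPR4 at 2.66 and 2.31, TGA3 at 2.81 and 2.17, and TGA2 (AHBP-1B in the reference table) at 2.32 and 2.17, from 1 peak that also counts for TGA5 of the same list. Intracellular NLR receptors had 11 of 26 bound against 10.98 (adjusted exact p = 1), with RPS6 at 2.01 and 1.91 and SNC1 at 1.97 and 1.84. Camalexin and glucosinolate metabolism had 6 of 19 bound against 7.27 (adjusted exact p = 0.868), with CYP83B1 at 2.84 and 2.42, PEN2 at 2.67 and 2.18, and GSTF6, a member of a family of similar genes, at 1.98 and 1.75. The named peaks of CPK28, NPR4 and CYP83B1, like those of JAZ6 and EIN3, also lie near another gene.

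When only summits inside the gene were counted, a rule added after summit positions had been seen, 4 of these lists passed with more genes than expected, as did 3 sets outside immunity, and 2 sets passed with fewer. Pattern-recognition receptors and early signalling then had 14 genes against 4.99 expected (adjusted exact p = 0.00244), jasmonate and ethylene 14 against 5.07 (adjusted exact p = 0.00244), salicylic acid 13 against 4.88 (adjusted exact p = 0.00341), and early elicitor-responsive genes 8 against 2.80 (adjusted exact p = 0.0217). NLR receptors had 4 against 5.36 (adjusted exact p = 1), and camalexin and glucosinolate genes 5 against 3.37 (adjusted exact p = 0.755). Outside immunity, housekeeping genes had 10 against 3.61 (adjusted exact p = 0.00953), photosynthesis genes 11 against 4.46 (adjusted exact p = 0.0196) and ribosomal proteins taken by name 16 against 6.91 (adjusted exact p = 0.00762). Cytochromes P450 had fewer, 21 against 41.0 (adjusted exact p = 0.00244), as had the Polycomb list given below.

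Single immune genes named in advance differed. BAK1, the co-receptor of many pattern-recognition receptors, had 2 shared peaks, the better on chromosome 4 from 16090593 to 16091893 with its replicate 1 summit 65 bp inside the gene and a fold of 2.13. The matching replicate 2 peak of 2.28 has its summit over 500 bp from the gene. The other replicate 2 peak there had 2.14. ICS1 (EDS16 in the reference table), which encodes the main enzyme of pathogen-induced salicylic acid synthesis, had 1 on chromosome 1 from 28073732 to 28074824 with its summit 99 bp inside (2.69 and 1.99). NPR1, a salicylic acid receptor gene, had 1 on chromosome 1 from 23855481 to 23855810 with its summit 24 bp inside (1.95 and 2.03). FLS2, the flagellin receptor gene, had a peak in each replicate (1.49 and 2.54) that did not count as shared. WRKY33 had 3 and EDS1 had 2 peaks in replicate 1 and none in replicate 2. No peak of either replicate lay near FRK1 or PR1, genes commonly used as markers of pattern-triggered and salicylic acid responses. A gene without a listed peak may still be enriched below the authors' threshold, which depends on depth.

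Outside immunity, 3 of the 12 other lists were bound more often than genes of their length: housekeeping and cytoskeleton genes, which are active in most cells, nuclear photosynthesis genes, and canonical histone genes, which are active when DNA is copied. Of the housekeeping and cytoskeleton list, 17 of 20 genes were bound against 7.72 expected (adjusted exact p = 0.00065), including ACT2 with 2 shared peaks (the better 3.18 and 2.37), UBC9 (2.70 and 2.70) and the elongation factor gene EF1A1 (2.96 and 2.42, 1 of several near-identical copies). Of 35 nuclear photosynthesis genes 22 were bound against 10.9 (adjusted exact p = 0.00134), with LHCA4 at 2.68 and 2.50 and the plastocyanin gene PETE2 (DRT112 in the reference table) at 2.38 and 2.43. Of 13 canonical histone H3 and H4 genes 7 were bound against 2.26 (adjusted exact p = 0.022), with a histone H4 gene (AT3G53730) at 3.17 and 2.40 and HTR3 at 2.55 and 3.46. These histone genes are near-identical copies and the treatment of reads with several matches is not known, although 5 of the 7 bound ones have their summits outside the gene only. Cytosolic ribosomal protein genes of the fixed list did not pass (16 of 28 against 9.67, adjusted exact p = 0.0685), with RPL5B at 3.01 and 2.65 and RPL10A (SAC52 in the reference table) at 2.54 and 2.79. This list passed in 3 of 12 alternatives: a −log10 q of at least 5 in both (10 bound, 2.84 times expected, adjusted exact p = 0.0388), replicate 1 alone (0.014) and Fisher's exact test (0.0459). Of 12 alternatives, 3 ended the housekeeping call (adjusted exact p from 3.28e-05 to 1), among them a −log10 q of at least 5 in both (7 bound, 0.185), and 5 ended the photosynthesis call (2.4e-05 to 1), among them replicate 1 alone (27 bound, 0.149). The histone call ended in 8 (adjusted exact p from 0.00241 to 1), among them Fisher's exact test without length bins (0.270).

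Of 4 lists of genes that are off in most seedling cells, the seed list passed the test with fewer bound genes than expected. The other 3 also had fewer but did not pass, and no test set the lists apart. None of the 17 seed storage and embryo maturation genes was bound against 4.98 expected (0%, 0 to 18.4; adjusted exact p = 0.0199), among them the embryo regulator genes ABI3 and LEC2, which had no peak in either replicate. Of 28 developmental regulators silenced by Polycomb proteins in leaves 5 were bound against 11.4 (adjusted exact p = 0.0604), with AP1 at 2.26 and 2.07 and AP3 at 2.08 and 2.57, both with the summit outside the gene. FLC had 1 peak in replicate 1 only. Markers of root, stomatal, trichome and vascular cells had 3 of 21 bound against 7.86 (adjusted exact p = 0.0864), with EXPA7 at 1.85 and 1.95 and MUTE at 1.65 and 1.67. Pollen and sperm-cell genes had 4 of 15 against 5.71 (adjusted exact p = 0.840), with HTR10 (MGH3 in the reference table) at 2.42 and 2.15 and AGL65 at 2.16 and 1.91. With summits inside the gene only, the Polycomb list had 0 genes against 5.53 (adjusted exact p = 0.0157) and the seed list 0 against 2.12 (adjusted exact p = 0.469). The seed list call ended in 8 of 12 alternatives (adjusted exact p from 0.00488 to 1), among them replicate 2 alone (1 bound, 0.184 times expected, 0.0579). The Polycomb list and the cell-type markers each passed in 3 (smallest adjusted exact p 0.00236 and 0.00517).

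The remaining lists did not pass the test. Circadian clock and light signalling had 13 of 22 bound against 9.002 (adjusted exact p = 0.247), with PIF3 at 2.59 and 2.52 and PIF5 (PIL6 in the reference table) at 2.63 and 2.36. Abiotic stress and abscisic acid response had 10 of 21 against 7.71 (adjusted exact p = 0.692), with ERD10 at 2.57 and 2.18 and CBF2 at 2.88 and 2.14. Chromatin regulators had 9 of 21 against 8.93 (adjusted exact p = 1), with the histone demethylase gene REF6 at 2.59 and 2.27 and the DNA methyltransferase gene MET1 at 2.29 and 2.16. Growth hormone pathways had 8 of 22 against 8.65 (adjusted exact p = 1), with the kinase gene BIN2 at 3.10 and 2.92 and the cytokinin receptor gene AHK4 (WOL in the reference table) at 2.66 and 2.25. With the nearest gene to each summit the growth hormone list had 16 bound (2.02 times expected, adjusted exact p = 0.00355). In replicate 1 alone the clock list had 22 (adjusted exact p = 0.014) and the abiotic stress list 20 (0.0241). Over 12 alternatives the largest adjusted exact p of each list was 1.

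Among 9 families taken from gene names, cytochromes P450, enzymes of specialised and hormone metabolism, were bound less often, and cytosolic ribosomal proteins, which make up the translation machinery, more often than genes of their length. Of 234 P450 genes 52 were bound against 88.9 expected (adjusted exact p = 7.21e-06), and of 50 ribosomal protein genes 30 were bound against 16.3 (adjusted exact p = 0.000942). WRKY factors (25 of 71 against 25.9, adjusted exact p = 1), NB-LRR proteins (12 of 26 against 10.5), receptor-like kinases (56 of 144 against 59.5), F-box proteins (17 of 45 against 15.5), heat shock proteins (15 of 35 against 13.4), defensin-like proteins (12 of 94 against 16.5) and glutathione transferases (13 of 49 against 14.8) did not pass (adjusted exact p from 0.465 to 1). Through its symbol RPS6, the bound ribosomal protein gene RPS6A (AT4G31700) was counted with the NB-LRR proteins and left out of the ribosomal family. In replicate 1 alone, receptor-like kinases (adjusted exact p = 0.0286) and defensin-like proteins (0.0355) had fewer bound genes than expected, and heat shock proteins (0.0216) and glutathione transferases (0.0218) more. Defensin-like proteins also had fewer with Fisher's exact test without length bins (adjusted p = 5.62e-05), and the largest adjusted exact p of each of these 4 families over 12 alternatives was 1. Of 12 alternatives, 2 ended the ribosomal call (adjusted exact p from 4.25e-07 to 1). Among them were the peaks near 1 gene only (14 bound, 1.58 times expected against 1.84 in the main test, adjusted exact p = 0.407). The P450 call also ended in 2 (1.04e-06 to 1). Among them was a −log10 q of at least 5 in both (20 bound, 0.602 times expected against 0.585 in the main test, adjusted exact p = 0.0748).

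**Figure D3:**
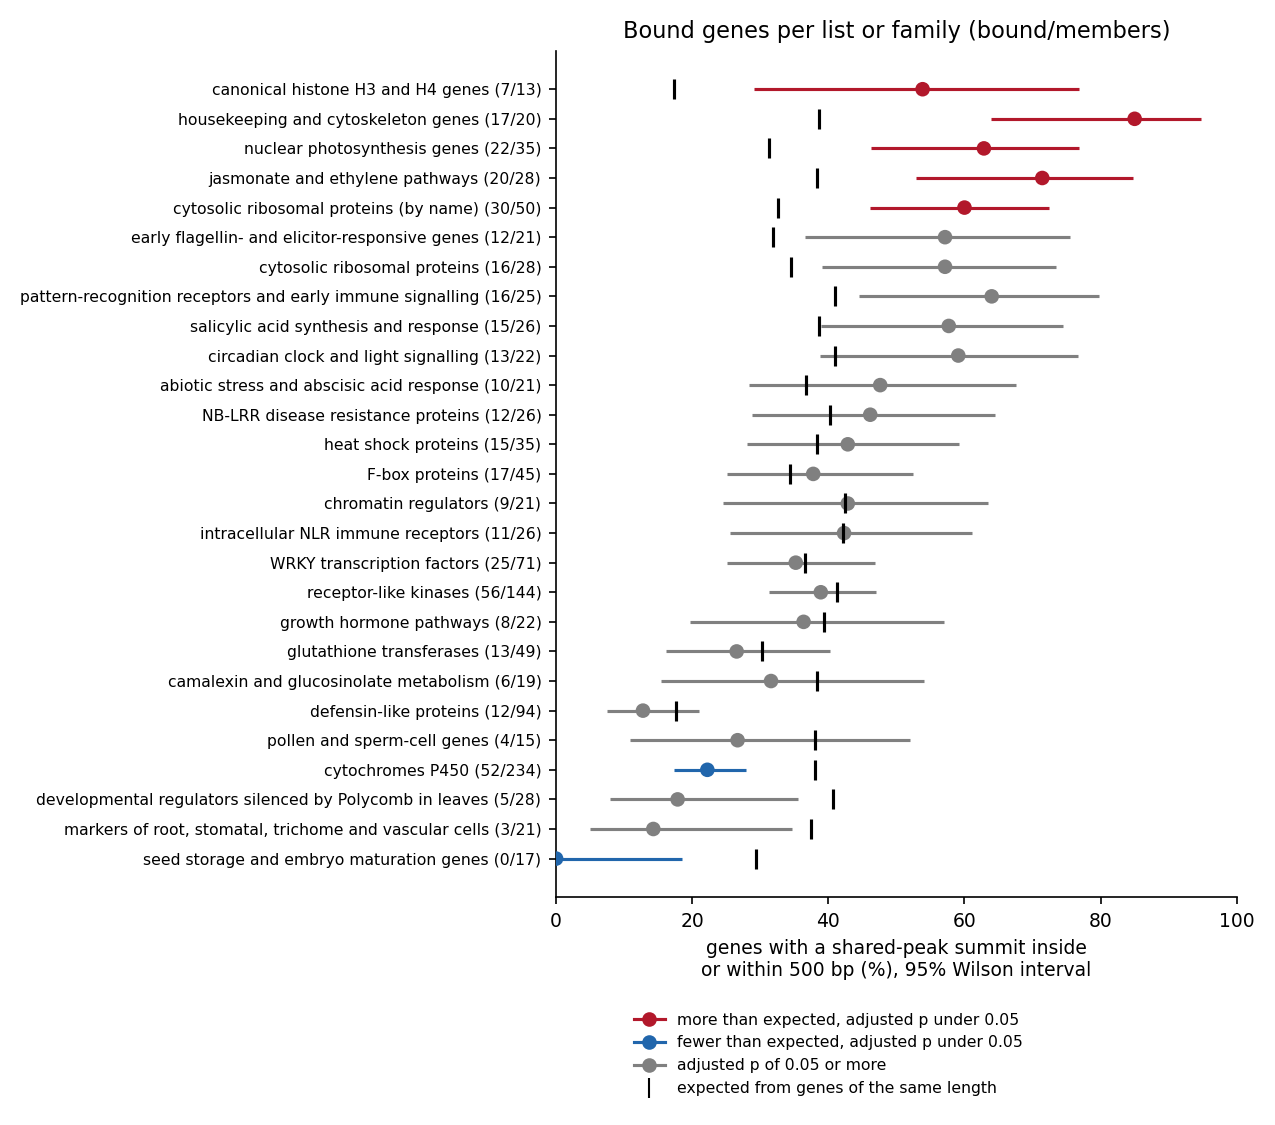
Share of genes with a shared-peak summit inside or within 500 bp (x axis, %, points with 95% Wilson intervals) for each of 18 lists and 9 families, with the share expected from genes of the same length as a black tick. Red marks more and blue fewer bound genes than expected at an adjusted p under 0.05; housekeeping genes reach 85.0% and seed storage genes 0%.

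Gene classes beyond protein-coding genes fell on both sides. Of 625 tRNA genes 372 had a shared-peak summit inside or within 500 bp (59.5%, 55.6 to 63.3) against 33.5% expected from genes of their length (exact length-stratified test, Benjamini-Hochberg adjusted p = 1.03e-61 over 11 classes). Summits lay a median of 43 bp from the tRNA gene. Pseudogenes had 49 of 3917 (1.25%, 0.948 to 1.65) against 28.7% expected, with an exact p too small to be represented. Transcribed pseudogenes had 79 of 926 (8.53%) against 21.9% (adjusted exact p = 1.08e-28). A planned class of transposable element genes is not among the 11 classes. Whether the pseudogene classes hold such genes was not checked. The test matches length only, not place along the chromosomes, and gene-poor windows held few peaks. MicroRNA genes had 51 of 326 (15.6% against 29.4%, adjusted exact p = 2e-09) and antisense RNA genes 13 of 79 (16.5% against 32.0%, adjusted exact p = 0.00368). Expected shares come from genes of all classes, so for short genes the tRNA genes raise them. Of the shortest protein-coding genes (median length 372 bp) 12.8% were bound. A microRNA deficit against short genes other than tRNA genes was therefore not tested. The same limit holds for the snRNA and snoRNA classes. The antisense call ended in replicate 1 alone (40.5%, 0.797 times expected there, adjusted exact p = 0.0777). The smallest adjusted exact p over 7 alternatives was 4.94e-05. Long non-coding RNA genes had 749 of 3480 (21.5% against 18.45%, adjusted exact p = 1.91e-09). This excess turned into a deficit (0.743 times expected) with Fisher's exact test without length bins. It ended at a −log10 q of at least 5 in both (7.13%, 1.05 times, adjusted exact p = 0.402; smallest over 7 alternatives 3.26e-31). Pseudogenes, which have few summits, lower the shares expected from genes of all classes. By the same test protein-coding genes also had more than expected (34.2% against 30.6%). An excess of long non-coding RNA genes over genes other than pseudogenes was not tested. The snRNA, snoRNA, misc RNA and other ncRNA classes did not pass the test (adjusted exact p from 0.124 to 0.708). Many tRNA genes have identical copies elsewhere and many lie near protein-coding genes: 358 of 496 tRNA genes within 1000 bp of one had a summit (72.2%), and 14 of the 129 others (10.9%, 6.58 to 17.4).

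**Figure D4:**
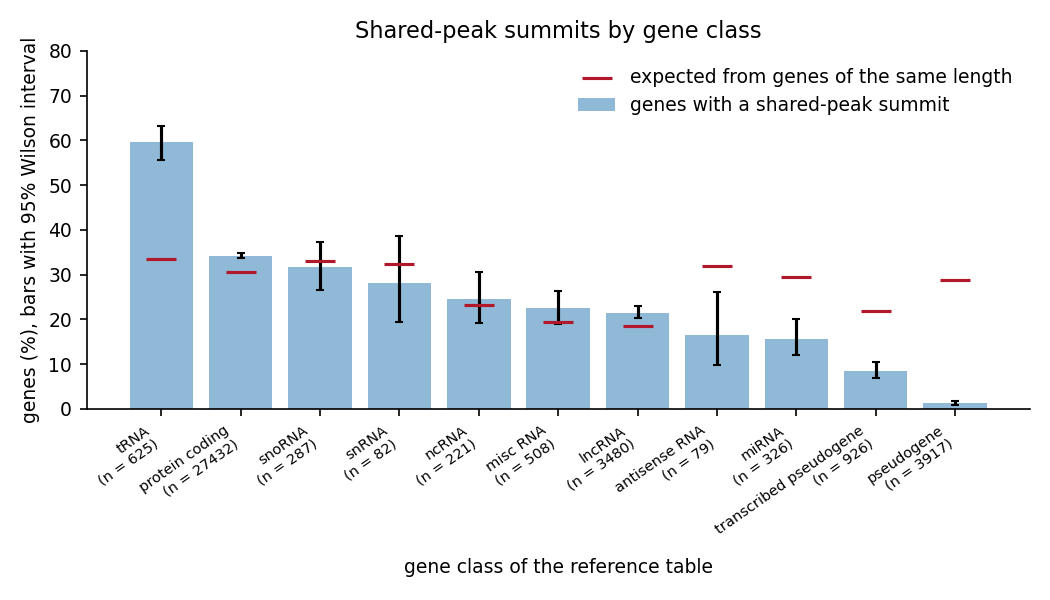
Share of genes with a shared-peak summit inside or within 500 bp (bars, %, with 95% Wilson intervals) by gene class of the reference table, with the share expected from genes of all classes and the same length as a red dash. The tRNA bar stands at 59.5% and the pseudogene bar at 1.25%.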

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

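The rules of a summit inside the gene, of the nearest gene and of peaks near 1 gene only, and Fisher's exact test for the gene classes, were chosen only after the data were seen. Results that kept their direction and their side of the threshold in all settings run were, among others, the share of summits at the outer 10% of gene length on each side (6 settings), the correlation of peak and gene density (4 settings) 3 of the 5 location classes (8 settings), and the calls for tRNA genes, pseudogenes, transcribed pseudogenes, microRNA genes and protein-coding genes (7 settings each). The protein-coding call rests on an expected share that pseudogenes, with few summits, lower. The lower background of replicate 2 (22.1 against 54.1 fragments) limits which weak peaks can be called in both. The cause of the changes below was not tested. At a −log10 q of at least 5, replicate 2 kept 3965 peaks; at 10, replicate 1 kept 10055 and replicate 2 569. Shared peaks numbered 3502 (q 5), 447 (q 10) and 4917 (reciprocal overlap), and the correlation of strength was 0.248 (q 5), 0.363 (reciprocal) and 0.297 (by −log10 q). The intergenic share was below chance at q 10 (13.2%), with 1000 bp windows (12.1%) and in replicate 1 alone (19.0%, adjusted permutation p = 0.004), and ran from 19.0% to 22.9% without either replicate; the class inside genes near an end was 38.8% with 1000 bp windows. Bound genes numbered 3419 (q 5), 529 (q 10), 4561 (reciprocal), 4193 (inside), 5196 (near 1 gene) and 10160 to 18291 without either replicate.

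Lists with more bound genes were 4. At q 5 there was 1, the fixed cytosolic ribosomal list, which is not among those 4. There were 0 at q 10, 1 with reciprocal overlap, 2 near 1 gene only and 5 to 8 without either replicate. Lists with fewer were 1, but 0 at q 5, q 10, reciprocal overlap, nearest gene and near 1 gene only, 3 with any overlap of the gene body, and 0 to 3 without either replicate. Families with more bound genes were 1, but 0 at q 10 and near 1 gene only and 1 to 3 without either replicate; families with fewer were 1, but 0 at q 5 and q 10, 2 with Fisher's exact test and 1 to 3 without either replicate. Gene classes with more summits were 4 to 7 without either replicate. Of the called results, long non-coding RNA genes turned with Fisher's exact test (21.5%, 0.743 times expected), and the photosynthesis list stood at 0 bound at q 10 (adjusted exact p = 1), a count too low to show a direction. Of the results that were not called, 5 were called on the opposite side in some setting: growth hormone genes with the nearest gene (16 bound, 2.02 times expected), glutathione transferases in replicate 1 alone (39 bound, 1.303), misc RNA with Fisher's exact test (0.775), snRNA in replicate 1 alone and with summits inside (1.26 and 2.16), and snoRNA in replicate 1 alone (1.12). Of 66 named genes, 18 changed between bound and unbound at q 5, 38 at q 10, 17 with reciprocal overlap, 25 with summits inside the gene, 19 with peaks near 1 gene only, 10 with the nearest gene and 6 or fewer in each other setting. No paired analysis was possible because all tests lie within 1 group. Not run, for want of strand and sequence, were the rule of 500 bp around the transcription start and every setting of the sequence at summits.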

Other observations

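The tests in this part were chosen only after the result they bear on had been seen, except the depth test, whose 1.5-fold bound was set before its value was known. A scan of 240 groups of genes that share the start of their symbol, each with at least 8 members, gave 3 groups with more and 4 with fewer bound genes than genes of their length (exact test, Benjamini-Hochberg over the scan). Polyubiquitin and related UBQ genes (10 of 13 bound against 3.97 expected), ADF genes for actin-depolymerising factors (9 of 11 against 3.32) and RPL genes for large-subunit ribosomal proteins (15 of 22 against 7.01) were bound more often. MYB transcription factor genes (24 of 120 against 41.3), SCPL genes for serine carboxypeptidase-like proteins (9 of 49 against 20.4) and LAC genes for laccases (0 of 14 against 5.81) were bound less often, each of these 6 groups with an adjusted p of 0.0399, as were the CYP genes already described. With summits inside the gene 17 groups had an unadjusted p under 0.05 in the same exact test and 0 after adjustment.

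Genes with a shared summit at both ends were more frequent than under a permutation that kept gene length only. Of 14442 protein-coding genes of at least 2 kb, 926 had a summit within 500 bp of each end, against 766 ± 21.6 (SD) when the marks of one end were permuted among genes of similar length (1.21 times, two-sided permutation p = 0.002, the smallest that 1000 permutations give), and 4790 had one at a single end. Place along the chromosome was not kept, and shared peaks per gene went from 0.0419 in the gene-poorest windows to 0.354 in the richest. Whether such regional differences give the excess was not tested. The 5 widest replicate 1 peaks, named after they were seen, overlapped PEN3 (7260 bp), MST1 (6160 bp), AT4G27652, AT4G27654 and AT4G27657 (5475 bp), SAT32 and ACA1 (5143 bp), and AT1G61890 (4350 bp). Against 10000 random draws of equally strong peaks, 2 of 24 lists and families differed in median width at an unadjusted p under 0.05 in each replicate and 0 after adjustment, with smallest adjusted permutation p of 0.293 in replicate 1 and 0.425 in replicate 2.

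Replicate 1 had 1.93 times as many peaks as replicate 2. Depth may account for it: scaled to the background of replicate 2, 19911 replicate 1 peaks would still pass, 1.496 times the number called there, just within the 1.5-fold bound set in advance. At the smallest p of replicate 2, a cutoff added after that value was seen, the ratio was 1.51, just outside it, so the share due to depth cannot be told apart from a difference in enrichment. The background used for scaling also depends on fragment length, taken as 210 and 150 bp. Scaling by the ratio of reads alone (1.95) was not run. No biological explanation was tested, as both replicates belong to 1 group.

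Peaks were frequent near tRNA genes and genes used in every cell and rare at pseudogenes and seed storage genes. A candidate explanation is that open or transcribed chromatin is recovered more readily by any immunoprecipitation. It predicts few bound genes in 3 other lists silent in most seedling cells (pollen, Polycomb targets and cell-type markers). Of their 64 pooled members 12 were bound, 0.481 times the 24.96 expected (exact test, p = 0.000783). Each of these lists already had fewer bound genes than expected in the single tests above, so the pooled p is no independent support. The low share would equally hold if DEK2 itself binds open or transcribed chromatin, and without an untagged immunoprecipitate both stay open. Reads with several matches left out of repeats could lower the 1.25% of pseudogenes with a summit, and this cannot be told apart without knowing which pseudogenes have unique sequence.

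Members of the 6 immunity lists carried summits inside the gene more often than genes of their length (58 of 145 against 26.5, exact test, p = 1e-09; 80 against 56.0 with the 500 bp rule, p = 6.2e-05), where pooling and the inside rule were both chosen after the single lists had been seen. Peaks of a neighbouring gene are unlikely to account for it, since with only the peaks near 1 gene the pooled ratio was 2.36 (43 against 18.2, exact p = 5.72e-08). For a general excess in lists of well-studied regulators, 4 lists outside immunity were pooled, with summits inside the gene. Their ratio was 1.24 (20 of 86 against 16.1, exact p = 0.346, upper limit 1.79), below the ratio of 2.19 for immunity (direct comparison in 5 classes of gene length, exact p = 0.00918). These 4 lists were chosen after the data were seen, and none had passed alone with summits inside the gene. The comparison therefore cannot decide on a general excess. With the nearest gene these 4 lists had an excess too (1.31, exact p = 0.0424). The values that follow use the 500 bp rule, by which the shared peaks gave 1.17 for these 4 lists and 1.43 for immunity. In replicate 1 alone the 4 lists had 1.22 (exact p = 0.000102) and the immunity pool 1.14 (exact p = 0.00253). By this rule the immunity pool did not pass at a −log10 q of at least 5 (25 against 20.5, exact p = 0.336) or at 10 (6 against 3.14, 0.190). Nor did it pass with reciprocal overlap (33 against 27.7, exact p = 0.305). Pooled summits inside the gene were not tested in these settings. Housekeeping (10 against 3.61) and photosynthesis genes (11 against 4.46) also had an excess inside genes, open chromatin was not tested, and no biological explanation was tested.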
